A study of Homo sapiens with 6 samples.

How the data were processed

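RNA was measured by sequencing in 3 human cell lines, with 2 libraries per line and 6 libraries in all. One library of each line carries a label of 25M reads and the other a deeper one. For the deeper MCF10A library the labels disagree, giving 100M reads in the title and 50 in the sample type. Groups were taken from the cell line labels. Both HT-29 libraries are labelled as stimulated with IFN-γ at 200 U per ml for 24 hours, and untreated HT-29 cells were not analysed here. Nothing in the labels says whether the libraries of a line came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

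FastQC, STAR 2.2.0, HTSeq and the genome build hg19 are named in the submitters' processing notes, with no role or settings. The gene annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Reads of near-identical family members (keratins, HLA genes, MAGEA genes, histones) are uncertain in the same way. Each deposited table holds, per the file headers, a gene symbol, a normalised count and an RPKM value in 23368 rows. The deposited normalised counts are a signal scaled by 1 factor per library: 100% of the values above 0 were whole multiples of 1 step within a tolerance of 0.001, so whole reads could be recovered. The recovered totals were 18.3 and 69.5M reads for MCF10A, 18.4 and 50.2M for the libraries labelled HT-29 with IFN-γ, and 16.7 and 56.4M for those labelled MDA-MB-436. The deposited RPKM values were out of register with the gene symbols in 3546 rows, 15.2% of all, and all 23368 rows came into register once the RPKM column was taken to be in case-insensitive order. Gene lengths implied by the displaced rows had a Spearman correlation across genes with annotated transcript lengths of 0.802 if the symbols belong to the normalised counts and of 0.263 if they belong to RPKM. RPKM was therefore used for this check only. As deposited, 28 symbols read as dates and 4 rows had a repeated name. These rows were left out, which kept 23340 names, of which 22075 matched a current or older RefSeq symbol.

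The test fixed before the data were examined was edgeR's quasi-likelihood test on raw counts. The deposited unit is a normalised count, so limma took its place, with a trended and robust prior on log2(normalised count + 1), for genes with a normalised count of at least 10 in at least 2 libraries. All 6 libraries entered 1 fit with 3 residual degrees of freedom and 15638 genes. A gene differed at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. For deeper against 25M libraries, with cell line as a block, the rule fixed beforehand was the adjusted p alone, with no fold minimum. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Folds quoted in words are ratios of pooled reads with 95% counting intervals, and a group at 0 reads was set to a floor of 3 reads over the group. Intervals and floors cover counting error only. Adjusted p-values in the text are limma's, and those of gene lists are from limma's camera with a preset correlation of 0.01, adjusted over all lists and comparisons. Values with an estimated correlation are from camera with that correlation taken from the data. That version reads p on the 3 residual degrees of freedom, so its p-values can be large whatever the correlation. edgeR and DESeq2 on the recovered reads served as alternatives. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

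The median chi-square of the paired libraries over genes was 0.566 for MCF10A, 0.730 for the libraries labelled HT-29 and 0.705 for those labelled MDA-MB-436, where sampling alone gives 0.455. A rule set beforehand would have ended testing had all lines been under 0.6, which they were not. As MCF10A alone was under it, its libraries were also summed as 1 sample.

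Before the data were examined, 25 gene lists and a panel of genes were fixed, of which 24 lists had tested members. Counts of list members are over the tested genes only. A member near 0 in a line is tested only if it reaches the filter in another line, which favours counts of higher genes there. Genes named are the 6 with the largest change in each direction with at least 20 CPM in the higher line and no overlap of libraries, up to 2 members per list and direction, and the panel. A few genes that this rule names are not reported here. For read depth the 3 genes with the smallest p in each direction are named. On simulated counts, 0 of 67 genes changed 1.5-fold, which is under the fold threshold, 67 of 67 changed 3-fold and 66 of 66 changed 8-fold were recovered for MDA-MB-436 against MCF10A, with 2 false calls among 13309 genes. The other line comparisons recovered as many, except 66 of 67 changed 3-fold for HT-29 against MDA-MB-436. For deeper against 25M libraries, with no fold minimum, 46 of 67 genes changed 1.2-fold were recovered, 64 of 67 changed 1.5-fold and 64 of 66 changed 2-fold, with 10 false calls among 13305. Of those changed 1.2-fold 2 had the wrong sign. All lines in the simulation were given the MCF10A means and a common dispersion for every gene, unlike the real libraries. The real depth comparison also gave fewer small p-values than expected with no difference, so these recoveries do not measure its power. Alternatives covered the scaling, filter, pseudocount, thresholds, test, thinning to equal depth, a depth block and leaving out each library. Those with TMM in limma, other pseudocounts and the summed MCF10A libraries were chosen after seeing the data. The test fixed beforehand, edgeR with TMM, was run on the recovered reads as an alternative that was added then too.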

Results

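Gene expression was compared between MCF10A, a non-tumorigenic mammary epithelial line, HT-29, a colorectal adenocarcinoma line labelled as stimulated with IFN-γ, and MDA-MB-436, a breast carcinoma line. Each line had 2 libraries, and recovered totals ran from 16.7 to 69.5M reads. Values are normalised read counts, as mean ± SD with n = 2 libraries. The genes high in the libraries labelled MDA-MB-436 and in those labelled HT-29 go against these labels, as described for each comparison. Samples were kept in their labelled groups, and every direction below holds for the libraries as labelled.

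**Figure D1:**
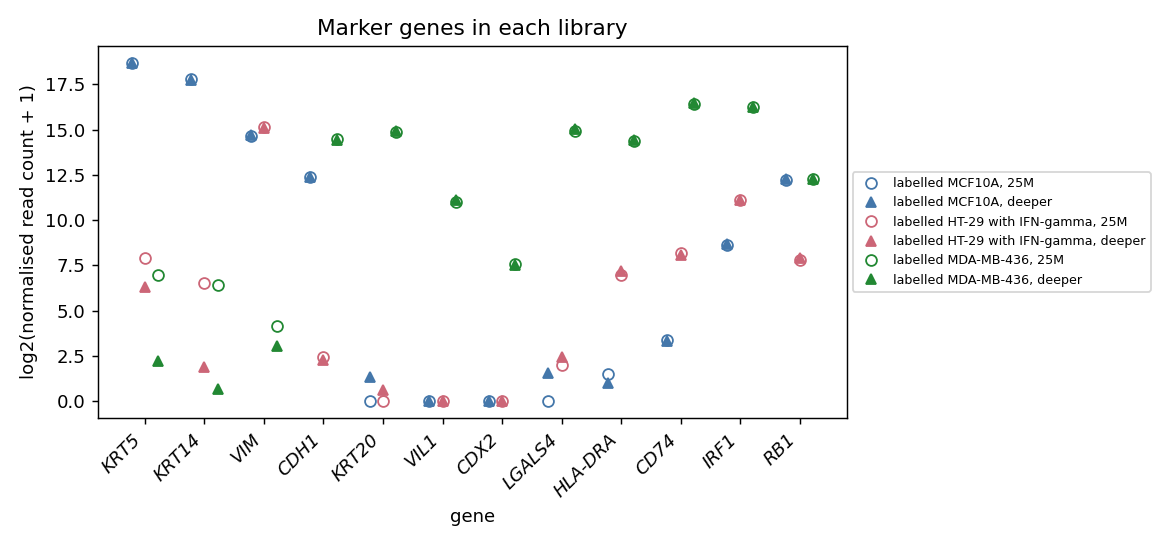
Normalised read counts on a log2(value + 1) axis for 12 marker genes in the 6 libraries, with open circles for 25M libraries and filled triangles for deeper ones. KRT20 averaged 30390 in the libraries labelled MDA-MB-436 and 0.274 in those labelled HT-29, while VIM averaged 11.9 and 35930.

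The first comparison asked how the libraries labelled MDA-MB-436 differed from MCF10A. They were high in interferon-induced, antigen presentation and intestinal genes and nearly lacked basal keratins and vimentin. GBP4, an interferon-induced guanylate-binding protein, averaged 37980 ± 557 against 0.736 ± 1.04 in MCF10A, a log2 fold change of 14.56 (SE 0.381, adjusted p = 6.86e-08). KRT20, an intestinal keratin, averaged 30390 ± 693 against 0.736 ± 1.04, and LGALS4, an intestinal galectin, 32710 ± 1617 against 0.982 ± 1.39. KRT5, a basal keratin, averaged 63.6 ± 84.7 against 420100 ± 5598 in MCF10A.

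All 27 tested genes of the IFN-γ list were higher (adjusted p = 3.57e-10 by camera; adjusted p = 0.113 with an estimated correlation). CXCL11, a chemokine, had 18216 reads against 1. The transcription factor IRF1 was 194.2-fold higher, GBP1 694.3-fold and the checkpoint ligand CD274 86.4-fold. CXCL10 was 4001-fold higher (interval 1714 to 12320), and IDO1, with 0 reads in MCF10A, at least 1087-fold. All 24 type I interferon genes were also higher (adjusted p = 1.20e-09; adjusted p = 0.113 with an estimated correlation), among them MX1 at 13240 ± 294 against 6.45 ± 1.48. Of 19 MHC class I genes 17 were higher and 1, CALR, was lower (adjusted p = 2.53e-07; adjusted p = 0.179 with an estimated correlation). All 13 MHC class II genes were higher (adjusted p = 1.87e-05; adjusted p = 0.113 with an estimated correlation). CD74, the invariant chain, averaged 88480 ± 2585 against 9.10 ± 0.372, HLA-DRA 21360 ± 559 against 1.43 ± 0.630, and the class II transactivator CIITA 8842 ± 73.5 against 0.736 ± 1.04. The labels record no IFN-γ for these libraries.

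Of 22 intestinal genes 21 were higher and 1 was lower (adjusted p = 1.13e-05; adjusted p = 0.147 with an estimated correlation). CDX2, an intestinal transcription factor, averaged 188 ± 8.36 and VIL1, which encodes villin, 2126 ± 101, both with 0 reads in MCF10A, so at least 158.1-fold and 1856-fold higher. Of 17 luminal genes 11 were higher and 3 lower (adjusted p = 0.0140; adjusted p = 0.147 with an estimated correlation), with KRT19 up and KRT7 down. Of 24 junction genes 15 were higher and 3 lower (adjusted p = 0.00204; adjusted p = 0.305 with an estimated correlation). CDH1 was 4.24-fold and EPCAM 16.0-fold higher.

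Of 21 basal genes 17 were lower and 0 higher (adjusted p = 5.79e-06; adjusted p = 0.113 with an estimated correlation). TP63 averaged 3.91 ± 0.298 against 2908 ± 103. KRT14 had a log2 fold change of -14.21 (adjusted p = 0.0176) and KRT81 of -12.64 (adjusted p = 0.0102). Without the deeper library labelled MDA-MB-436 the log2 fold changes were -11.35 and -11.73, and both calls ended. That fit took its spread from the MCF10A libraries and those labelled HT-29. In the latter KRT14 stood at 91.5 and 2.7 and KRT81 at 88.5 and 1.6. Of 25 mesenchymal genes 19 were lower and 1 higher (adjusted p = 1.26e-04; adjusted p = 0.147 with an estimated correlation). VIM averaged 11.9 ± 6.42 against 26070 ± 244. SFRP1, a secreted Wnt inhibitor, and FBN2, a fibrillin, were among the 6 largest decreases, as was BNC1, with 0 reads and at least 5169-fold lower. LYZ, which encodes lysozyme, and the chemokine CX3CL1 were among the 6 largest increases.

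The MAPK output list had 11 higher and 2 lower of 20 (adjusted p = 0.00309; adjusted p = 0.147 with an estimated correlation), led by EREG. Glucocorticoid response had 4 higher and 11 lower of 18 (adjusted p = 0.0111; adjusted p = 0.147 with an estimated correlation). Only the MCF10A medium is labelled as holding hydrocortisone. Cell cycle had 12 lower of 28 (adjusted p = 1.10e-05; adjusted p = 0.113 with an estimated correlation) and cholesterol synthesis 2 higher and 15 lower of 24 (adjusted p = 6.54e-05; adjusted p = 0.113 with an estimated correlation). p53 targets had 4 higher and 13 lower of 22 (adjusted p = 0.00256; adjusted p = 0.138 with an estimated correlation), and glycolysis and hypoxia 5 higher and 8 lower of 29 (adjusted p = 0.0145; adjusted p = 0.508 with an estimated correlation). The remaining 9 lists did not pass. CDKN2A and MTAP, neighbours on the short arm of one chromosome, had 3 and 5 reads in MCF10A against 11904 and 9633. RB1 averaged 4897 ± 47.6 against 4823 ± 96.8 and did not differ (adjusted p = 0.623). ERBB2 (log2 fold change 0.94), EGFR (-0.93) and ZEB1 (-0.62) stayed under the fold threshold, and ESR1 was lower (-1.44). EGFR passed with TMM scaling (-1.03) and with limma-voom, and the call of ESR1 ended with all libraries thinned to equal depth (-0.87, adjusted p = 0.0743) and when tested against a fold of 2 (adjusted p = 0.267).

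In all, 7701 of 15638 genes differed, 3999 higher and 3702 lower, and 1531 and 1227 differed at least 8-fold. With a filter of at least 10 CPM in 2 libraries 2424 were higher and 2655 lower, and with TMM scaling 3755 and 4008. The median SE was 0.0718.

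The second comparison asked how the libraries labelled HT-29 with IFN-γ differed from MCF10A. They had little E-cadherin and basal keratin, high levels of some cancer-testis antigens, and no detected villin or CDX2. CDH1, which encodes E-cadherin, averaged 4.17 ± 0.474 against 5316 ± 12.4 in MCF10A, a log2 fold change of -10.01 (SE 0.066, adjusted p = 4.28e-11). MAGEA4, a cancer-testis antigen, averaged 31770 ± 447 against 5.55 ± 2.56. CDX2 and VIL1 had 0 reads in these libraries and in MCF10A. These libraries, labelled as a colorectal line, thus carried 0 reads of 2 intestinal panel genes.

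Of 22 intestinal genes 5 were higher, 4 lower and 13 did not pass (adjusted p = 0.989). Of 24 junction genes 20 were lower and 2 higher (adjusted p = 8.02e-07; adjusted p = 0.147 with an estimated correlation), with ST14 3334-fold and EPCAM 13.1-fold lower. TJP3, 1 of the 2 higher genes, fell under the fold threshold with edgeR and TMM (log2 fold change 0.933) and with limma-voom (0.927). Of 21 basal genes 19 were lower and 1, OXTR, was higher (adjusted p = 6.74e-07; adjusted p = 0.113 with an estimated correlation). KRT14 (log2 fold change -13.54, adjusted p = 0.0199) and KRT5 (-11.59, adjusted p = 0.0104) lost their calls without the deeper library labelled HT-29. Their log2 fold changes were then -11.23 and -10.80. That fit took its spread from the MCF10A libraries and those labelled MDA-MB-436. In the latter KRT14 stood at 84.4 and 0.6 and KRT5 at 123.5 and 3.7. KRT81, KRT6A, S100A14, SPRR1B and TNS4 were with KRT14 the 6 largest decreases. Of 17 luminal genes 9 were lower and 2 higher (adjusted p = 0.0296; adjusted p = 0.173 with an estimated correlation). Of 25 mesenchymal genes 15 were higher and 4 lower (adjusted p = 0.0234; adjusted p = 0.305 with an estimated correlation). COL6A2 averaged 8748 ± 11.4 against 7.76 ± 5.68, and ZEB1, a repressor of E-cadherin, was 6.83-fold higher. VIM averaged 35930 ± 942 against 26070 ± 244 (adjusted p = 0.320). That p used a spread shared with the libraries labelled MDA-MB-436, where VIM stood at 16.5 and 7.4, and not only that of the lines compared.

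Interferon genes were higher here too. The IFN-γ list had 22 higher and 1, SECTM1, lower of 27 (adjusted p = 2.76e-06; adjusted p = 0.113 with an estimated correlation), with IRF1 5.38-fold, GBP1 19.3-fold, CXCL10 101.9-fold and CD274 3.86-fold higher. CIITA averaged 46.7 ± 10.3, HLA-DRA 135 ± 14.9 and IDO1 10.6 ± 4.37. The type I list had 22 higher of 24 (adjusted p = 1.72e-08; adjusted p = 0.113 with an estimated correlation), with IFI6 at 20020 ± 140 against 26.3 ± 10.7. MHC class I had 11 higher and 1 lower of 19 (adjusted p = 3.05e-04; adjusted p = 0.317 with an estimated correlation), and class II 11 higher of 13 (adjusted p = 0.00910; adjusted p = 0.147 with an estimated correlation). The NF-κB and cytokine list had 19 higher and 1 lower of 22 (adjusted p = 5.93e-05; adjusted p = 0.137 with an estimated correlation), including CCL2 at 2164 ± 55.9 against 4.08 ± 0.476.

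All 10 tested genes of the 23 on the cancer-testis list were higher (adjusted p = 0.00477; adjusted p = 0.147 with an estimated correlation), with levels from that of MAGEA12, 2.94 ± 2.03 against 0 reads in MCF10A, to that of MAGEA4. Of these 10 genes 5 had 0 reads in MCF10A and could pass the filter only through another line, so the filter partly fixed this count. MAGEA12 passed it through the libraries labelled MDA-MB-436, at 77.1 ± 12.9. The other large increases, besides MAGEA4, were FBLN2, an extracellular matrix protein, CDKN2A, BCAT1, ARMCX3 and BHMT2. RB1, the retinoblastoma tumour suppressor, averaged 229 ± 8.32 against 4823 ± 96.8, 20.9-fold lower. MTAP was 931-fold higher (interval 398.7 to 2869), EGFR lower at 2287 ± 37.7 against 9150 ± 148.5, ESR1 25.9-fold lower and TP63 153.3-fold lower. ERBB2 had a log2 fold change of -1.04, and of -0.73 with scaling by library size alone, which ended its call, as did a test against a fold of 2 (adjusted p = 0.316). Glucocorticoid response had 1 higher and 11 lower of 18 (adjusted p = 0.00162; adjusted p = 0.138 with an estimated correlation), cholesterol synthesis 12 lower of 24 (adjusted p = 9.19e-05; adjusted p = 0.113 with an estimated correlation) and p53 targets 1 higher and 15 lower of 22 (adjusted p = 1.27e-04; adjusted p = 0.113 with an estimated correlation). Cell cycle had 2 higher and 4 lower of 28 (adjusted p = 0.0360; adjusted p = 0.173 with an estimated correlation).

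In all, 7265 genes differed, 4442 higher and 2823 lower, with 1969 and 603 at least 8-fold. Scaling by library size alone moved the median log2 fold change by 0.31 and gave 5445 higher and 1989 lower. With a filter of at least 10 CPM in 2 libraries the split was 2209 higher and 2181 lower.

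The third comparison set the libraries labelled HT-29 with IFN-γ against those labelled MDA-MB-436. Epithelial, intestinal and IFN-γ genes were higher in the libraries labelled MDA-MB-436, and mesenchymal genes in those labelled HT-29. KRT20 had 1 read in the libraries labelled HT-29 and 64661 in the others, a log2 fold change of -14.58 (SE 0.426, adjusted p = 1.69e-08). FBLN2 averaged 30470 ± 605 in the libraries labelled HT-29 against 8.13 ± 8.88.

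Of 22 intestinal genes 21 were lower and 1 higher in the libraries labelled HT-29 (adjusted p = 1.10e-05; adjusted p = 0.147 with an estimated correlation). All 24 junction genes were lower (adjusted p = 3.77e-09; adjusted p = 0.146 with an estimated correlation), with CDH1 5626-fold and EPCAM 209-fold lower, and 14 of 17 luminal genes were lower and 3 higher (adjusted p = 9.84e-04; adjusted p = 0.138 with an estimated correlation). KRT19, MUC13, TRIM31, CEACAM6 and KLK6 were with KRT20 the 6 largest decreases. Of 25 mesenchymal genes 24 were higher and 1 lower (adjusted p = 4.56e-06; adjusted p = 0.138 with an estimated correlation). The 1 lower gene, COL6A3, averaged 1.84 against 4.94, and its call ended with edgeR, DESeq2 and limma-voom. VIM was 3756-fold higher, and CDH2, which encodes N-cadherin, had 11161 reads against 1. ZEB1 was 10.6-fold higher. PRAME and CRMP1, with 0 reads in the libraries labelled MDA-MB-436, were at least 3203-fold and 2659-fold higher, and MAGEA4, UCHL1 and BASP1 were among the 6 largest increases.

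Although IFN-γ is recorded for the libraries labelled HT-29, 26 of 27 IFN-γ genes were lower there and 0 higher (adjusted p = 3.77e-09; adjusted p = 0.113 with an estimated correlation). IRF1 was 36.1-fold, GBP1 36.0-fold, CXCL10 39.3-fold, IDO1 105.4-fold and CD274 22.4-fold lower. All 13 MHC class II genes were lower (adjusted p = 6.04e-05; adjusted p = 0.113 with an estimated correlation), with CIITA 204.9-fold and HLA-DRA 154.2-fold lower, and 15 of 19 class I genes were lower and 1 higher (adjusted p = 3.31e-06; adjusted p = 0.219 with an estimated correlation). Type I interferon genes went both ways, 15 lower and 2, HERC5 and IFI6, higher of 24 (adjusted p = 1.26e-04; adjusted p = 0.138 with an estimated correlation). The call of IFI6 (log2 fold change 1.23) ended when tested against a fold of 2 (adjusted p = 0.443). NF-κB and cytokine genes were 14 higher and 1 lower of 22 (adjusted p = 0.00950; adjusted p = 0.171 with an estimated correlation), led by CCL2 and IL6.

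RB1 had a log2 fold change of -4.41 in the libraries labelled HT-29. The list of tumour suppressors and oncogenes had 2 higher and 12 lower of 23 (adjusted p = 0.00423; adjusted p = 0.246 with an estimated correlation), MAPK output 2 higher and 12 lower of 20 (adjusted p = 0.00256; adjusted p = 0.147 with an estimated correlation), and cell cycle 10 higher and 1, MKI67, lower of 28 (adjusted p = 0.00950; adjusted p = 0.147 with an estimated correlation). With scaling by library size alone MKI67 had a log2 fold change of -0.97 and lost its call. ERBB2 was 3.92-fold lower. ESR1 was 8.48-fold lower, at 2.12 ± 0.874 against 23.3 ± 7.75, and TP63 5.07-fold higher, at 20.8 ± 4.59 against 3.91 ± 0.298. ESR1 and TP63 thus had few reads in the libraries compared. EGFR had a log2 fold change of -1.07, and of -0.74 with scaling by library size alone, which ended its call, as did a test against a fold of 2 (adjusted p = 0.0793). CDX2 and VIL1, with 0 reads in the libraries labelled HT-29, were at least 153.4-fold and 1800-fold lower. CDKN2A (adjusted p = 0.571), KRT5 (adjusted p = 0.311) and MTAP (log2 fold change -1.33, adjusted p = 0.0741) did not pass, but MTAP passed in 10 alternative settings, with edgeR, DESeq2 and limma-voom among them. The shared spread of CDKN2A and MTAP included the MCF10A libraries, at 0 and 1.5 and at 0 and 2.5. Without the 25M library labelled MDA-MB-436 the log2 fold change of KRT5 was 4.86, against 2.49 with all libraries.

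**Figure D2:**
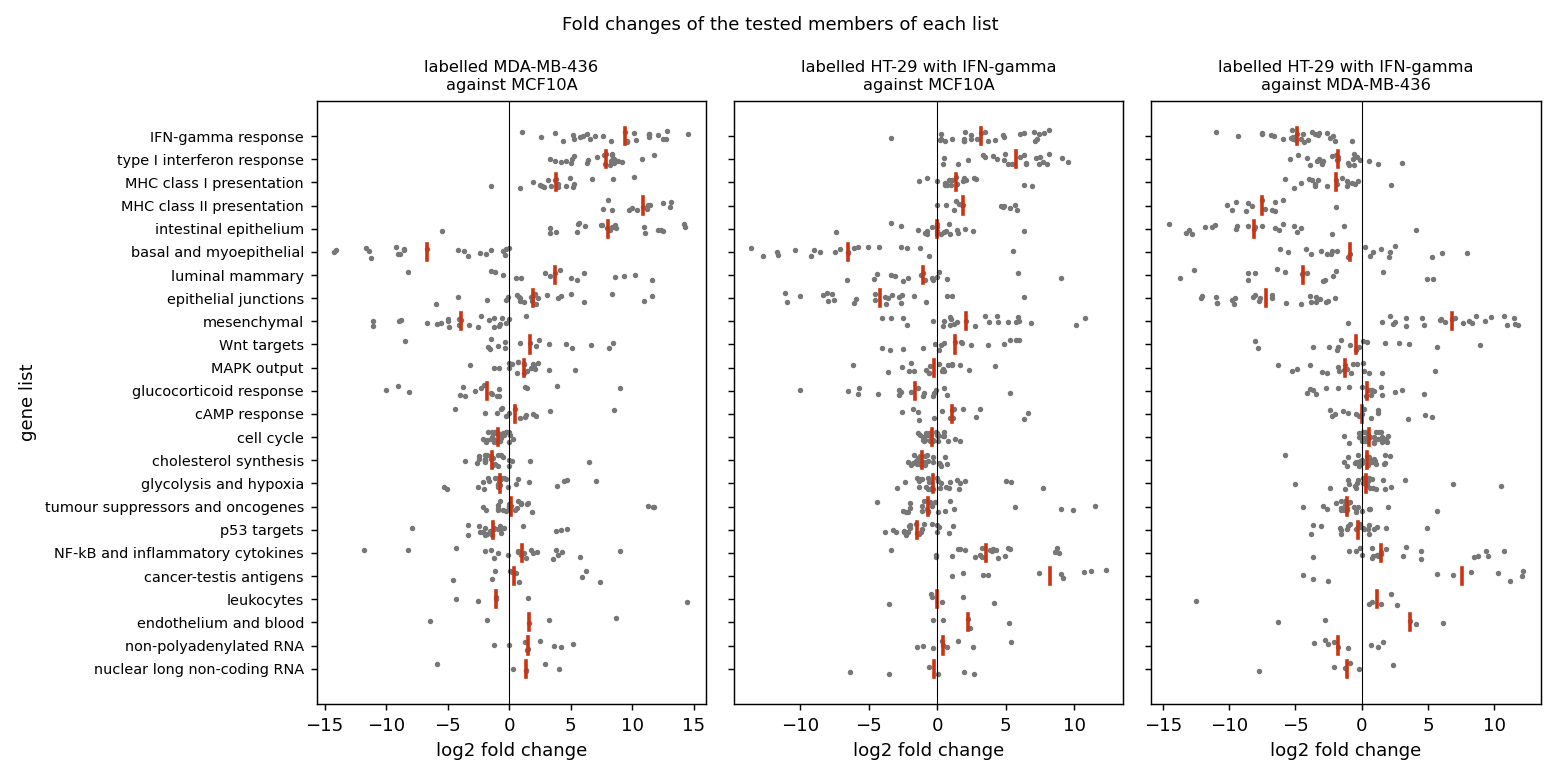
Log2 fold changes (horizontal axis) of the tested members of 24 gene lists (vertical axis) in the 3 comparisons, with a grey point per gene and a red bar at the median. In the third panel the intestinal median is -8.11 and the mesenchymal median 6.80.

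In all, 8350 genes differed, 4675 higher and 3675 lower, and 2241 and 1162 at least 8-fold. Scaling by library size alone moved the median by 0.327 and gave 5692 higher and 2797 lower. With the 10 CPM filter it was 2670 higher and 2637 lower. The lists that did not pass in any comparison were Wnt targets, cAMP response, leukocytes, endothelium and blood, non-polyadenylated RNA and nuclear long non-coding RNA, with adjusted p-values of 0.418, 0.578, 0.559, 0.800, 0.0684 and 0.0853 in the first comparison. Counts of list members were identical when adjusted over the list alone.

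The last comparison asked what deeper sequencing added within each line. MCF10A had 15494 genes with at least 1 read in the 25M library and 16935 in the deeper one. The libraries labelled HT-29 had 17557 and 18578, and those labelled MDA-MB-436 15809 and 16931. The mean gain was 1194.7 ± 219.2 genes (SD, n = 3 lines), and it ended once the deeper libraries were thinned to the totals of their partners, with a mean difference of -65.3 genes. The gain is a net number, as 280, 332 and 364 genes were seen only in the 25M library, in the same order of lines. Genes seen only in the deeper library had a median of 1, 2 and 2 reads. At thresholds of 5 and 10 reads the mean gains were 1313.3 and 1314.7 genes. Between depths, at an adjusted p below 0.05 with no fold minimum, 0 genes differed by limma, 0 by DESeq2 and 1 by edgeR, and 284 had an unadjusted p below 0.05, where 782 would be expected with no difference. The smallest p-values belonged to RGS7, MIR93 and ELMOD2, higher in the deeper libraries, and BIN2, SLC36A1 and MIR4691, lower there (adjusted p = 0.9999 for each).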

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

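Among the settings tried, those with TMM in limma, pseudocounts of 0.5 and 5, and summed MCF10A libraries were chosen after seeing the data. The run of edgeR with TMM, the test fixed beforehand, on the recovered reads was added then too. A filter of at least 10 CPM in 2 libraries lowered the counts of differing genes to 5079, 4390 and 5307 in the 3 comparisons in the order of the report, because fewer genes were tested. edgeR with TMM on the recovered reads called 7803, 7461 and 8495 genes. Leaving out each library in turn gave 7072 to 7514, 5998 to 7074 and 7113 to 8293 genes, where a line left with 1 library is assumed to vary like the others. With an estimated correlation between genes 0, 0 and 0 lists passed. As that version reads p on 3 residual degrees of freedom, it cannot tell correlation between members from the small number of libraries. The directional fry test, which does not compare a list with other genes, passed 22, 23 and 24 lists. Between depths edgeR called 1 gene with either scaling and limma 0, with 284 genes at an unadjusted p below 0.05 against 782 expected with no difference; the cause of the 1 call was not tested. Thinning the deeper libraries took away the gain in detected genes, by construction of equal depth. The mean difference was then -65.3, with -41 in MCF10A, -45 in the line labelled HT-29 and -110 in that labelled MDA-MB-436. The cause of this deficit was not tested. Without thinning, leaving out each line gave gains of 1071.5 to 1281.5.

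With depth class as a replicate block the counts were 7715, 7271 and 8360. The deviations of libraries of like depth had correlations across genes of -0.003, 0.007 and 0.028, so depth was not taken to pair the libraries. For named genes under planned settings, 5129 values kept their direction and side of the threshold, 40 fell below it, 10 rose past it and 0 reversed. This tally leaves out edgeR with TMM. Many named genes were chosen for large changes in these same libraries, and the settings refit the same reads. The tally therefore says little about genes nearer the threshold. MTAP in the third comparison was called in 10 settings, among them edgeR with either scaling, DESeq2, limma-voom, the 4 compared libraries alone and each fit without 1 MCF10A library. Genes with few reads are limited by depth, as the counting intervals show.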

Other observations

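The tests of gene families and the tests of mixing, displaced rows, carried-over reads and sample splits were chosen after the results were seen; the 3 second gene lists were written before their genes were looked up, though after the fixed lists had shown the direction.

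The 17 gene families, taken by symbol, were tested first with all members and then without members of the fixed lists; the second version is given here, where 18 of 51 tests passed. Ribosomal protein genes had 1 higher and 33 lower of 71 in the libraries labelled HT-29 against MCF10A (adjusted p = 2.18e-08 by limma's camera; adjusted p = 0.545 with an estimated correlation). They had 1 higher and 7 lower in those labelled MDA-MB-436 against MCF10A (adjusted p = 1.54e-04; adjusted p = 0.606 with an estimated correlation), and 2 higher and 16 lower in the libraries labelled HT-29 against those labelled MDA-MB-436 (adjusted p = 0.00264; adjusted p = 0.668 with an estimated correlation). With library size alone, the median of all genes moved by 0.31 against MCF10A and 0.327 against MDA-MB-436 for the libraries labelled HT-29. Ribosomal medians there were -0.916 and -0.372, so these counts depend on the scaling. By share of reads, ribosomal protein genes held 3.71% and 3.66% in the libraries labelled HT-29. The shares were 3.76% and 3.97% in those labelled MDA-MB-436 and 5.49% and 5.40% in MCF10A. In the libraries labelled MDA-MB-436 against MCF10A, 7 of 9 HOXB genes were higher and 1 lower (adjusted p = 0.0240), 7 of 7 claudins (0.0120), 7 of 8 mucins (0.0250) and 5 of 5 UDP-glucuronosyltransferases (0.0443) were higher, and 9 of 9 small proline-rich and late envelope genes of squamous cells were lower (0.00979). For each of these the adjusted p was 0.308 with an estimated correlation. In the libraries labelled HT-29 against MCF10A, 9 of 9 small proline-rich and late envelope genes (adjusted p = 0.00744), 9 of 10 kallikreins (0.00731) and 6 of 9 clade B serpins (0.0120) were lower, and of 476 zinc finger genes 167 were higher and 34 lower (0.0120), each with adjusted p = 0.308 with an estimated correlation. S100 genes had 1 higher and 6 lower of 14 (adjusted p = 0.0120; adjusted p = 0.456 with an estimated correlation). In the libraries labelled HT-29 against those labelled MDA-MB-436, 9 of 11 HOXA (adjusted p = 0.0148), 8 of 9 HOXB (0.00932), 8 of 10 kallikrein (0.0120) and 5 of 5 UDP-glucuronosyltransferase genes (0.0340) were lower, and of 24 collagens 19 were higher and 1 lower (0.00728), each with adjusted p = 0.308 with an estimated correlation.

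The intestinal and IFN-γ genes were high in the libraries labelled MDA-MB-436, and a candidate explanation is that the labels of this line and of HT-29 with IFN-γ were exchanged. In lists that share no gene with the fixed ones, the median log2 fold change of the libraries labelled HT-29 against those labelled MDA-MB-436 was -7.45 over 20 colon genes, 3.79 over 20 mesenchymal breast genes and -2.84 over 28 IFN-γ genes, each in the direction an exchange needs. Mixed RNA is argued against, since the 10 most abundant mesenchymal genes stood in the libraries labelled MDA-MB-436 at a median of 0.116% of their level in the others, and so are displaced rows, since 18 intestinal genes differed in rows in register. These lists argue against a difference between the lines as labelled. It would need a colorectal line to lie below a breast line in 19 of the 20 colon genes, with 1 higher. It would also need IFN-γ genes to be lower in the line recorded as stimulated, as 21 of 28 were, with 3 higher. No reference profile of either line was used here, so the exchange itself was not shown. If the labels were exchanged, the first and second comparisons would change places and the third would change sign.

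Markers of a line were genes at 200 CPM or more there and under 1000 ppm of that level in the pooled reads of the other line. This choice used the same reads, most of them from the deeper library, and so favours a lower share there. MCF10A markers were found at a higher share of the MCF10A level in the 25M library than in the deeper one, at 588.1 and 124.9 ppm in the line labelled HT-29 (12 of 12 markers higher) and 390.1 and 100.0 ppm in that labelled MDA-MB-436 (14 of 18 higher, 3 lower), ratios of 4.71 and 3.90. KRT14 stood at 502.1 against 15.5 ppm and at 372.2 against 2.76, KRT81 at 464.2 against 8.82 and at 286.4 against 78.5, and KRT5 at 687.3 against 230.4 and at 289.7 against 8.72, in the same order of lines, and calls of these genes ended without 1 library while their fold changes stayed large. For 15 markers of the libraries labelled HT-29 the line labelled MDA-MB-436 held 597.5 and 140.5 ppm, a ratio of 4.25, while the other 3 pairs of lines had ratios of 0.905, 1.2 and 0.949. Low expression at 1 level in both libraries of a line would not give the KRT14 values, but the summed ratios did not reach the bound of 5 set for excluding low expression, and as the libraries may come from separate cultures it stays open. Reads carried over from the MCF10A 25M library are a candidate source for the MCF10A markers, not for the HT-29 ones, and were not settled: a first test, on the spread of the excess between markers, could not be computed as intended because the 10th percentile was -300.2 ppm in the libraries labelled MDA-MB-436, and a second test, added after that, gave a bootstrap p of 0.194 and 0.0300 for more scatter than counting around 1 share.

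For deeper against 25M libraries 0 genes differed by limma (284 at an unadjusted p below 0.05 against 782 expected with no difference, 1 by edgeR and 0 by DESeq2). With a real count of 0, each of the 10 splits of the 6 libraries gives as many by construction, so 10 of 10 says nothing about chance, and so few splits could not give a share below 0.05 in any case. The highest other value was 97 genes, in a pair of splits that are 1 and the same contrast of single libraries labelled MDA-MB-436.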
